A study of Saccharomyces cerevisiae with 5 samples.

How the data were processed

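Gene expression was measured on 5 oligonucleotide arrays of Saccharomyces cerevisiae, each hybridised with the labelled nucleic acid of 2 strains, one in Cy5 and one in Cy3. Per the labels, every culture had received 0.5 mol/L NaCl for 45 min. The arrays make up 3 comparisons. The strain bdf1Δ was set against its parent W303, a common laboratory strain, on 1 array with bdf1Δ in Cy5. The strain bdf1Δ+HAL2 and the double mutant bdf1Δhda1Δ were each set against bdf1Δ on 2 arrays with the dyes exchanged. Per the labels, the exchanged arrays repeat the same test and control sample, so each pair was counted as 1 replicate. No comparison therefore has replicates, and no p-value was computed. Errors given as SD are the spread between the 2 arrays of a pair, or between the 3 repeat spots of a gene on the single array. They cover technical variation only. On the single array the SD of repeat spots had a median of 0.17 over genes, while 144 control spots of ACT1 had an SD of 1.46. The SD given there therefore understates the technical variation, position on the slide included.

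The deposited scanner files hold the intensity of each spot and of its local background in the red and the green channel, per the file headers. They also hold a red-over-green ratio, per the file headers, which on the array of bdf1Δ versus W303 followed the spot medians without background subtraction. The image software and the scanner settings are not given in the sources used here. A separate table holds a linear ratio per probe made by the authors from the same arrays. Its columns were checked against the scanner values. All 5 run as test strain over reference strain, including the arrays with exchanged dyes. The authors' deposited ratio had a median of 0.194 for bdf1Δ versus W303, 0.990 and 1.01 for the bdf1Δ+HAL2 pair, and 1.00 and 1.04 for the bdf1Δhda1Δ pair. Scale and direction are thus known. The bdf1Δ versus W303 column is not centred, and how the other columns were centred stays unknown. This table was used as an alternative only.

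Spot medians and background medians were corrected by normexp with an offset of 50 and normalized within each array by global loess, with weight 0 for control spots and for spots the image software had not found (limma 3.58.1 in R 4.3.3). The sign was turned on the arrays with the test strain in Cy3. A spot was used when the image software had found it and at least 1 channel exceeded its background by 2 background SDs. A gene was measured when at least 2 of its 3 spots were used on every array of the comparison, and its value was the mean of those spots. Saturated spots were kept. Later steps used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

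The finding of spots by the image software mostly set how many genes could be measured. On array 1 of the bdf1Δhda1Δ pair, 6302 of the 6303 gene spots found were used. The bdf1Δhda1Δ channel exceeded its background there in 75.7% of the gene spots, found or not. The image software had found 58.5% of the 19164 gene spots on the bdf1Δ versus W303 array, 72.9% and 68.9% on the bdf1Δ+HAL2 pair, and 32.9% and 40.3% on the bdf1Δhda1Δ pair. On the bdf1Δ versus W303 array the bdf1Δ channel exceeded its background in 36.9% of the gene spots and the W303 channel in 91.2%. The median log2 ratio of that array before normalization was −1.73, and −2.37 in the authors' deposited ratio, so its changes are relative to the median gene. Position on the slide accounted for 35.8% of the variance of the ratios there, as the share between its 48 printing blocks. Across the other 4 arrays that share ran from 3.18% to 10.7%. The number of arrays limits the precision of every value.

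Probes carry systematic reading-frame names. Of 6388 gene probes, 5849 matched a locus tag of the R64 gene table, 5236 of which have a gene symbol of their own, and 539 matched none. The files name no genome build, so no coordinates are given. HAL2 is listed in that table as MET22. Cross-hybridisation of near-identical genes could not be examined because no sequences are given. Values of the ERR, PAU, ENA, HXT and paired ribosomal protein genes are therefore uncertain as to the copy.

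Genes were called higher or lower when the ratio exceeded 2-fold in the same direction on each array of the comparison, which is the rule the labels state. A strain is said to be not well above background for a gene when fewer than 2 of its 3 spots exceeded background in that channel on every array. The change is then also given as "at least", setting the brighter strain's mean level against the higher of the dim spots' own level and the lowest level seen above background, per channel after loess and Aquantile scaling. This was computed after global loess and, after the data were seen, after print-tip loess too, and the smaller of the 2 folds is given. It often equals the measured fold, and is then an estimate and not a guaranteed lower limit. It holds for these 2 normalizations only, and on the single array is open to dye bias and to position on the slide. The 24 gene lists, the rule for named genes, the calling rules and the alternatives listed in the closing section were fixed before the data were examined, except where the text says otherwise. A list of at least 5 measured genes was called higher or lower when its median fell in the top or bottom 2.5% of 10000 random lists matched in 10 bins of intensity, on each array of the comparison. These percentiles describe the arrays and are not tests between strains. Named genes are the targeted genes and BDF2, the 10 highest and 10 lowest called genes with a symbol, up to 4 called members of each list, and every called member of the iron uptake list. For bdf1Δ versus W303, this was narrowed, after the data were seen, to members of the iron, sodium and hyperosmotic lists and of the lists called. Further genes are said to have been chosen after their values were seen. Distance from a chromosome end was planned in kb and was replaced, after the files had been seen, by the rank of a gene from the end of its arm in systematic-name order.

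Because bdf1Δ enters all 3 comparisons, relations between them were set beside 200 simulations of unchanged strains sharing that strain. They assume 1 bdf1Δ extract on all arrays, which the labels do not state, so the simulated counts and correlations hold for that case only. The shared strain was assumed to carry 50% of the variance of the less variable comparison, with normally distributed ratios, and this assumption sets the simulated correlations. Simulated genes were called on their mean ratio. Normally distributed ratios put fewer genes of the modified strains past 2-fold than the data did. The simulated counts therefore run low and cannot weigh the observed ones. The steps were tested on simulated scanner data with 200 genes changed per comparison. Simulated spots carried small independent noise, and no gene-specific dye bias or variation between samples was simulated. The shares that follow check the steps and are not error rates of the real arrays. For bdf1Δ+HAL2 versus bdf1Δ (4267 genes), 100% of the measured genes changed 2.5-, 4- and 8-fold were called the right way, 0% of those changed 1.5-fold were, and 0 of 4124 unchanged genes were called. For bdf1Δhda1Δ versus bdf1Δ (2073 genes) these shares were also 100% and 0%, with 0 of 1994 unchanged genes called. For bdf1Δ versus W303 (3686 genes), simulated with block effects, 44.4% of the 2.5-fold, 86.7% of the 4-fold and 91.2% of the 8-fold changes were called the right way, 19.2% of the 1.5-fold changes were, and 38 of 3553 unchanged genes were called. With print-tip loess these shares were 66.7%, 83.3%, 97.1% and 0%, with 1 of 3553 unchanged genes called. A list shifted by 0.5 on the log2 scale was called in each comparison, and 3, 1 and 0 of 100 unchanged lists were called in bdf1Δ versus W303, bdf1Δ+HAL2 and bdf1Δhda1Δ, or 8, 0 and 0 with print-tip loess.

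Alternatives covered no background subtraction, normexp with offset 0, plain subtraction, median centring, print-tip loess (each block normalized on its own), scale normalization between arrays, the authors' ratios, other filters on dim and saturated spots, the median of repeat spots, other fold sizes, and each array of a pair alone. Control spots stayed out of all comparisons of strains.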

Results

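The data compare yeast strains under salt (0.5 mol/L NaCl, 45 min). BDF1 encodes a bromodomain protein that associates with the general transcription factor TFIID, and BDF2 is its paralogue. HAL2, listed as MET22, encodes a salt-sensitive phosphatase that removes a by-product of sulphate assimilation, 3'-phosphoadenosine 5'-phosphate. HDA1 encodes a histone deacetylase. The series asks, per its title, what HAL2 overexpression changes in bdf1Δ under salt. One array set bdf1Δ against W303, and 2 arrays with exchanged dyes set each of bdf1Δ+HAL2 and bdf1Δhda1Δ against bdf1Δ. Measured genes numbered 3688, 4266 and 2074 in these comparisons. Values are log2 ratios of the test strain over the reference strain.

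The targeted genes came first. BDF1 (YLR399C) gave a net intensity of 10 in bdf1Δ and of 510 in W303, where all 3 spots exceeded background. Its log2 ratio was −0.80 (−1.01 by print-tip loess), and W303 was at least 1.08-fold higher. The deleted gene was thus not called lower after global loess and had rank 820 from the lowest of 3688 genes. In the 9 channels holding bdf1Δ or a strain derived from it, BDF1 exceeded background in 0. HAL2 (MET22, YOL064C) was the most raised gene in bdf1Δ+HAL2, at 3.73 ± 0.15 (SD of 2 arrays), or 13.2-fold. In bdf1Δ against W303 it stood at −0.82, with bdf1Δ not well above background and W303 at least 1.21-fold higher. On the bdf1Δ+HAL2 pair, bdf1Δ gave HAL2 net intensities of 2384 and 3539.5, above background. The bdf1Δ versus W303 array thus gave a deleted gene and an expressed gene similar ratios. HDA1 (YNL021W) exceeded background in 0 spots of bdf1Δhda1Δ on either array, while bdf1Δ exceeded it in 2 of 3 spots on array 2, at a net intensity of 187, and in 0 on array 1. No ratio is given for HDA1, since the image software had not found those 2 spots and 0 of its spots were used on either array. BDF2 (YDL070W) lay at −0.50 ± 0.34 in bdf1Δ+HAL2 and 0.37 ± 0.02 in bdf1Δhda1Δ, within 2-fold in both.

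In bdf1Δ+HAL2 against bdf1Δ, genes of iron uptake were raised together. FIT3 (YOR383C) and FIT2 (YOR382W), cell wall mannoproteins that retain siderophore-bound iron, rose by 2.75 ± 0.35 and 1.69 ± 0.54. The surface reductases FRE1 (YLR214W) and FRE2 (YKL220C) rose by 1.55 ± 0.17 and 1.41 ± 0.35. FET3 (YMR058W) and FTR1 (YER145C), the ferroxidase and permease of high-affinity uptake, rose by 1.46 ± 0.08 and 1.34 ± 0.17. The siderophore transporters ENB1 (1.42 ± 0.10), ARN2 (1.37 ± 0.36) and SIT1 (1.14 ± 0.01) rose as well. Of 24 measured iron genes, 9 rose past 2-fold, 0 fell, and 15 lay within the rule, though all 24 ratios were above 0. The list median was 0.81, above 100% of the matched random lists on both arrays.

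By the 2-fold rule, 19 genes rose and 44 fell in this strain, and 0 moved past 2-fold in opposite directions on the 2 arrays. Scale normalization between arrays gave 32 and 63. The ratios of the pair correlated at Pearson r = 0.746 across genes, which are not independent replicates, with a median SD between arrays of 0.136. Among the 10 highest were INO1 (2.09 ± 0.02), the inositol-3-phosphate synthase, and PRM1 (1.89 ± 0.03), a membrane protein of mating-cell fusion. ARO10 (1.60 ± 0.03) and ARO9 (1.48 ± 0.03), enzymes of aromatic amino acid breakdown, and DUR12 (1.48 ± 0.09), the urea amidolyase, also rose. The deepest fall was that of KEX1 (YGL203C), a carboxypeptidase that processes α-factor and killer toxin, at −3.65 ± 0.31. It was followed by SHH3 (−2.55 ± 0.03), a homologue of a succinate dehydrogenase subunit, and by the enolase-related ERR2 (−2.05 ± 0.11), ERR1 (−1.94 ± 0.13) and ERR3 (−1.67 ± 0.53). RCK1 (−2.03 ± 0.19), a protein kinase, SIP18 (−1.70 ± 0.02), a salt-induced hydrophilin, and CMG1 (−1.60 ± 0.35) fell too. INO1, PRM1, KEX1, SHH3 and CMG1 had fewer than 2 spots with both channels above background on at least 1 array, so the size of their change is uncertain.

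Sterol synthesis was the other list called higher in bdf1Δ+HAL2. Its median was 0.58 over 22 genes, 20 of them above 0. None passed the rule, and ERG5 and ERG6, chosen after their values were seen, stood at 1.07 ± 0.10 and 1.03 ± 0.23.

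The lists called lower in bdf1Δ+HAL2 numbered 8. Seripauperins, near-identical cell wall proteins that act as one uncertain signal, had a median of −1.08 over 13 genes, of which 6 fell, including PAU22 (−1.66 ± 0.35), PAU19 (−1.50 ± 0.17), PAU15 (−1.36 ± 0.29) and PAU23 (−1.30 ± 0.30). Trehalose and glycogen genes had a median of −0.64 over 17 genes, 16 of them below 0 and 0 past 2-fold. Genes of mating type a stood at −0.75 over 6 genes, all below 0 and none past 2-fold. Galactose, maltose and hexose transport stood at −0.56 over 10 genes, where HXT2, a hexose transporter, fell (−1.48 ± 0.07). Respiratory chain genes lay at −0.21 over 35 genes, 31 of them below 0 with none called. Ribosome biogenesis genes lay at −0.20 over 37 genes, 34 of them below 0 with none called. Iron-sulphur and haem enzymes had a median of −0.15 over 25 genes, of which 1 fell, the cytosolic catalase CTT1 (−1.36 ± 0.05). Cell wall and anaerobic genes lay at −0.14 over 17 genes, of which 2 fell, PIR3 (−1.11 ± 0.04) and PAU23, which belongs to the seripauperins too. By print-tip loess that list median was −0.05 and PIR3 (−0.77) was not called. Members of the lists without a called gene were chosen after their values were seen: GIP2 (−0.90) and GLC3 (−0.77) of glycogen metabolism, BAR1 (−0.92) and STE2 (−0.77) of mating type a, NDE2 (−1.08) and QCR10 (−0.52) of the respiratory chain, and DBP2 (−0.62) and DBP3 (−0.49) of ribosome biogenesis.

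Sulphate assimilation, the pathway that HAL2 serves, was not called as a list. Its median was −0.19 over 15 genes, in the bottom 3.18% on array 1 and the bottom 0.185% on array 2. Within it 4 genes fell and 0 rose. They were MET17 (−1.60 ± 0.14), the sulphhydrylase of homocysteine synthesis, STR3 (−1.42 ± 0.04), cystathionine β-lyase, MET3 (−1.21 ± 0.20), ATP sulphurylase, and MET28 (−1.20 ± 0.24), a transcriptional regulator of the pathway, which was not called by print-tip loess (−1.09). Genes of sodium and potassium transport lay at −0.13 over 20 genes, with 0 called. The hyperosmotic list lay at −0.13 over 26 genes, of which SIP18 and CTT1 fell. Heat shock genes stood at 0.30 over 25 genes, with 0 called. The oxidative stress list lay at −0.00 over 26 genes, where CTT1 and the peroxiredoxin TSA2 (−1.25 ± 0.26) fell. Phosphate starvation (−0.13), general amino acid control (0.08), mitochondrial carriers and ribosome (−0.00), ribosomal proteins (0.10), selectable markers (−0.02) and chromatin partners (−0.01) were not called and held 0 called genes. Mitochondrially encoded genes, meiosis and mating type alpha had too few measured members, at 0, 2 and 1.

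**Figure D1:**
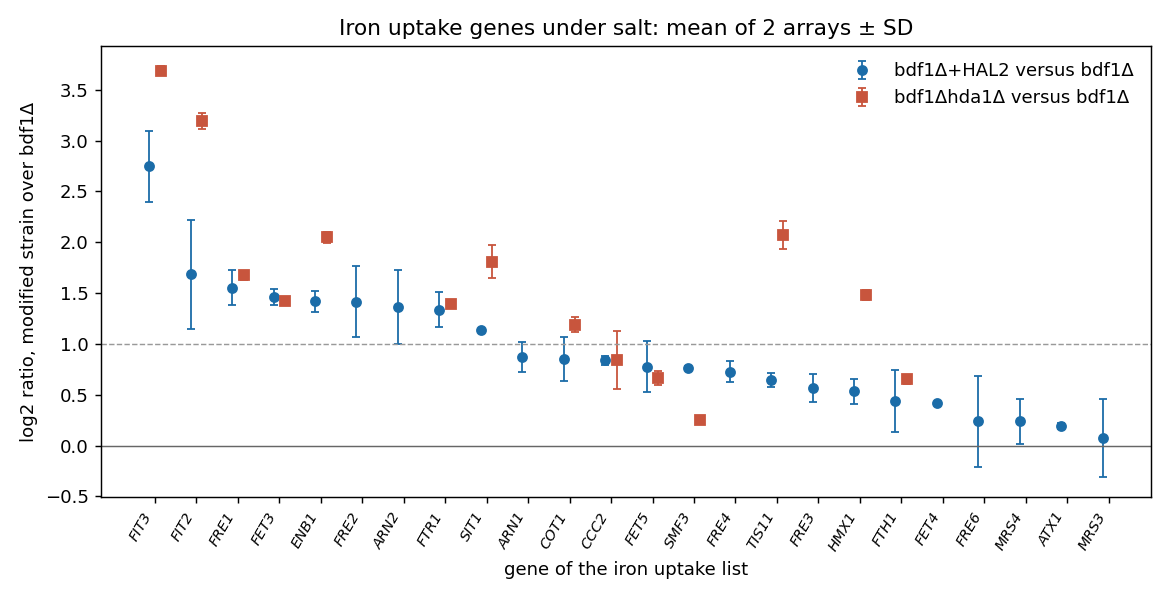
Log2 ratios over bdf1Δ of the measured genes of the iron uptake list, as the mean of 2 arrays with exchanged dyes, for bdf1Δ+HAL2 (circles) and bdf1Δhda1Δ (squares). Bars are the SD between the 2 arrays, the dashed line marks 2-fold, and FIT3 stands at 2.75 and 3.69.

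In bdf1Δhda1Δ against bdf1Δ, iron genes again led the genes that rose. FIT3 and FIT2 rose by 3.69 ± 0.04 and 3.19 ± 0.08, or 12.9-fold and 9.14-fold. TIS11 (YLR136C), an RNA-binding protein that promotes decay of mRNAs for iron-using proteins, rose by 2.07 ± 0.14. ENB1 (2.05 ± 0.05), SIT1 (1.81 ± 0.16), FRE1 (1.68 ± 0.05), HMX1 (1.48 ± 0.05), which encodes haem oxygenase, FET3 (1.42 ± 0.03), FTR1 (1.39 ± 0.04) and the vacuolar metal transporter COT1 (1.19 ± 0.07) followed. Of 14 measured iron genes, 10 rose, 0 fell and 4 lay within the rule, and the list median was 1.45, above 100% of the matched random lists on both arrays.

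The rule called 22 genes higher and 13 lower in bdf1Δhda1Δ, with 0 in opposite directions, and scale normalization between arrays gave 45 and 36. Across genes the 2 arrays correlated at Pearson r = 0.872, with a median SD between arrays of 0.0815. REE1 (1.52 ± 0.15), GTT2 (1.497 ± 0.005), a glutathione transferase, and FRE7 (1.495 ± 0.02), a reductase of the FRE family, were also among the 10 highest. The lowest was URA1 (YKL216W), dihydroorotate dehydrogenase, at −2.05 ± 0.04. FMP16 (−1.87 ± 0.15), the aquaporin AQY1 (−1.84 ± 0.32), the amino acid permeases GAP1 (−1.74 ± 0.01) and DIP5 (−1.31 ± 0.02), the Hsp70 gene SSA3 (−1.49 ± 0.08), RCK1 (−1.43 ± 0.04) and the stress gene DDR2 (−1.35 ± 0.08) fell. So did ARG1 (−1.22 ± 0.09), argininosuccinate synthase, and ACO1 (−1.21 ± 0.16), the iron-sulphur enzyme aconitase. TIS11, ENB1, SIT1, GTT2, FRE7 and AQY1 had fewer than 2 spots with both channels above background on at least 1 array, so the size of their change is uncertain.

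The lists called higher in bdf1Δhda1Δ numbered 5 with the iron list. Sterol synthesis had a median of 0.52 over 19 genes, all above 0 and none past 2-fold. The sulphate assimilation list had 0.50 over its 5 measured genes, none past 2-fold. For phosphate starvation the median was 0.32 over 13 genes, although its 1 called member, the membrane protein PHM7, fell (−1.01 ± 0.00). Oxidative stress genes had 0.22 over 19 genes, of which GTT2 rose. Examples chosen after their values were seen are ERG10 (0.98) and ERG13 (0.89) of sterol synthesis and the S-adenosylmethionine synthetases SAM1 (0.80) and SAM2 (0.72).

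The lists called lower numbered 6. General amino acid control had a median of −0.27 over 26 genes, of which ARG1 fell. For the respiratory chain it was −0.25 over 26 genes, of which SDH1 (−1.12 ± 0.00), a succinate dehydrogenase subunit, fell, though not by print-tip loess (−1.07). Iron-sulphur and haem enzymes lay at −0.21 over 16 genes, of which ACO1 fell, and ribosome biogenesis at −0.16 over 30 genes with none past 2-fold. Heat shock genes lay at −0.14 over 25 genes, where SSA3 fell and the membrane protein HSP30 (1.22 ± 0.04) rose. The hyperosmotic list lay at −0.12 over 19 genes, of which 2 fell, DDR2 and the glycerol symporter STL1 (−1.16 ± 0.15). MAK16 (−0.41) and RRP12 (−0.32) of ribosome biogenesis were chosen after their values were seen. Sodium and potassium transport (0.05), mitochondrial carriers and ribosome (0.07), trehalose and glycogen (0.07), cell wall and anaerobic genes (0.24), galactose, maltose and hexose transport (0.11), chromatin partners (0.04) and ribosomal proteins (−0.00) were not called and held 0 called genes. Mitochondrially encoded genes, meiosis, mating type a, mating type alpha, selectable markers and seripauperins had too few measured members, at 0, 1, 3, 0, 1 and 1.

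**Figure D2:**
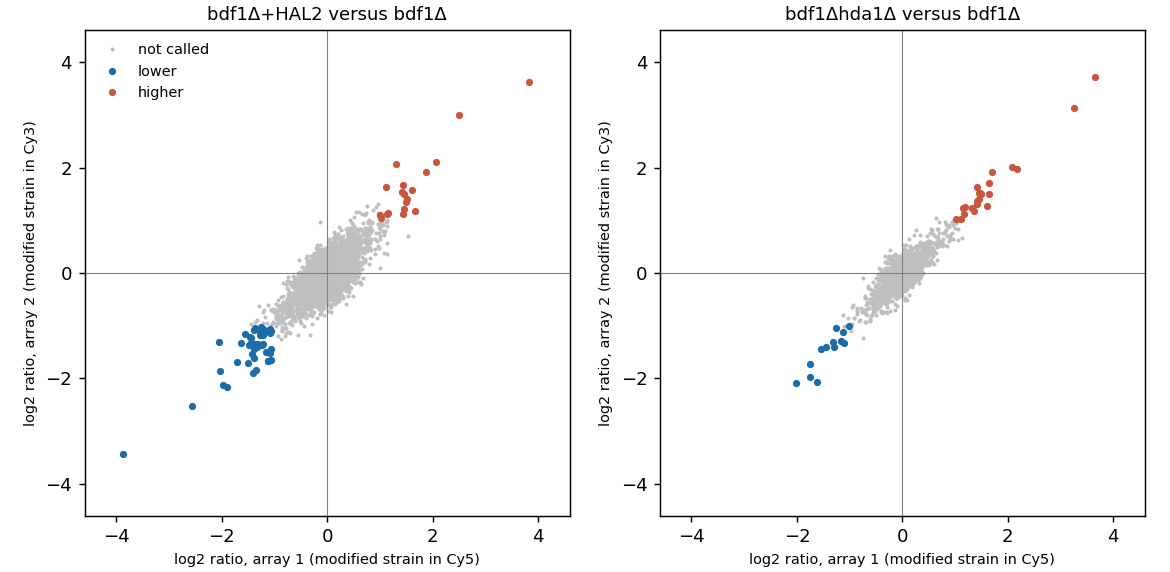
Log2 ratios of each measured gene on the array with the modified strain in Cy5 (horizontal axis) and on the array with exchanged dyes and turned sign (vertical axis), for bdf1Δ+HAL2 (left) and bdf1Δhda1Δ (right) over bdf1Δ. Coloured points passed 2-fold in the same direction on both arrays, 19 higher and 44 lower on the left and 22 higher and 13 lower on the right.

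Genes called the same way in both modified strains numbered 7 among those that rose. These were FIT3, FIT2, FRE1, FET3, ENB1, FTR1 and SIT1, all 7 from the iron uptake list. By print-tip loess SIT1 (1.06 in bdf1Δ+HAL2) was past 2-fold on 1 of the 2 arrays of that pair. Independent lists would share 0.102 such genes, and unchanged strains sharing bdf1Δ gave 0.325 in the simulation. FMP16 (−1.34 ± 0.17 in bdf1Δ+HAL2 and −1.87 ± 0.15 in bdf1Δhda1Δ) and RCK1 were the 2 that fell in both, against 0.126 for independent lists and 0.35 in the simulation. Fewer simulated than observed genes passed 2-fold, so both simulated counts run low and cannot weigh the observed ones. RGI1, a gene of respiratory growth, moved in opposite directions, at −1.16 ± 0.11 in bdf1Δ+HAL2 and 1.14 ± 0.03 in bdf1Δhda1Δ, but was not called in bdf1Δ+HAL2 by print-tip loess (−1.07). FMP16, in bdf1Δ+HAL2, and RGI1 were named after their values were seen. Across 2059 genes the comparisons correlated at Pearson r = 0.28 and Spearman rho = 0.22, with a covariance of 0.0360. Unchanged strains sharing bdf1Δ gave r = 0.44 and a covariance of 0.0562, values set by the share of variance given to bdf1Δ in the simulation.

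In bdf1Δ against W303, measured on 1 array, SPS100 (YHR139C), a spore wall gene, and PAI3 (YMR174C), an inhibitor of proteinase A, were the highest, at 3.32 ± 0.82 and 3.28 ± 0.19 (SD of 3 repeat spots). GPG1 (2.97 ± 0.41), FLO11 (2.72 ± 0.20), a flocculin, and IZH1 (2.502 ± 0.334) also rose. CCW12 (YLR110C), a cell wall mannoprotein, fell (−3.89 ± 0.31), as did PDC1 (−3.56 ± 0.42), pyruvate decarboxylase, and ENA1 (−2.20 ± 0.34), the sodium pump. All of these kept their call when each block of the slide was normalized on its own (print-tip loess), at 3.80, 3.06, 2.998, 2.27, 2.74, −3.64, −2.003 and −1.23.

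The rule called 587 genes higher and 679 lower, and print-tip loess 219 and 228, with 165 and 131 called by both methods. The bdf1Δ channel was not well above background in 384 of the 679 lower genes. The deleted BDF1, at −0.80, was not among the 679. With the authors' ratios, which are not centred, 31 genes were higher and 2873 lower, and scale normalization between arrays gave 2 and 28.

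Also among the 10 highest, with print-tip values second, were GAD1, glutamate decarboxylase (2.73 and 1.64), FAT3 (2.64 and 1.70), PHD1, a regulator of filamentous growth (2.64 and 1.10), HSP31 (2.53 and 1.20) and TMA17 (2.495 and 0.82). Among the 10 lowest, with print-tip values second, were RPL7B, a ribosomal protein (−4.03 and −0.24), SSB1, a ribosome-associated Hsp70 (−3.96 and 0.19), TMA19 (−3.64 and −0.09), the peroxiredoxin AHP1 (−3.59 and 0.09) and the reticulon RTN1 (−3.44 and −0.43). CPT1, cholinephosphotransferase, YNK1, nucleoside diphosphate kinase, and the cell wall gene CIS3 stood at −3.86, −3.60 and −3.51 but at −0.25, −1.15 and −0.04 by print-tip loess. They were not well above background in bdf1Δ, and W303 was at least 1.19-fold (CPT1) and 2.21-fold (YNK1) higher. For CIS3 the same rule gave 1.15-fold, more than its print-tip ratio of −0.04, so it is no lower limit there.

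Iron genes did not stand apart in bdf1Δ, with a list median of −0.05 over 16 genes, or −0.37 by print-tip loess. Of these, 2 rose, FRE1 (1.53 ± 0.10) and FRE2 (1.05 ± 0.13), the latter not well above background in bdf1Δ. The 4 that fell were HMX1 (−1.24 ± 0.23), FIT2 (−1.23 ± 0.12), SMF3 (−1.13 ± 0.10), a vacuolar metal transporter, and ENB1 (−1.05 ± 0.09), where W303 was at least 1.29-fold higher. Under print-tip loess only HMX1 of these passed 2-fold, at −1.15. In the sodium and potassium list, with a median of 0.24 over 18 genes, 3 rose and 3 fell. The pumps ENA2 (−1.61 ± 0.21) and ENA5 (−1.51 ± 0.41) fell with ENA1, while SAT4, a kinase of salt tolerance, rose (1.55 ± 0.39), and print-tip loess placed ENA2, ENA5 and SAT4 at −0.74, 0.15 and 0.23. In the hyperosmotic list, with a median of 0.18 over 25 genes, 7 rose and 7 fell. GPD1, glycerol-3-phosphate dehydrogenase, GRE2 and YPD1, a phosphorelay protein of osmosensing, fell (−2.97 ± 0.09, −2.94 ± 0.10 and −2.21 ± 0.13), and RTN2 rose (2.33 ± 0.06). None of these 4 passed 2-fold by print-tip loess (−0.57, −0.42, −0.16 and 0.76). GPD1, GRE2 and YPD1 were not well above background in bdf1Δ, and W303 was at least 1.49-fold, 1.33-fold and 1.12-fold higher.

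The list of mating type a was called higher, at 1.26 over 6 genes (0.72 by print-tip loess), of which 4 rose. They were the pheromone exporter STE6 (1.83 ± 0.04), the protease BAR1 (1.65 ± 0.33) and the pheromone genes MFA1 (1.43 ± 0.86) and MFA2 (1.08 ± 0.32). By print-tip loess MFA1 (1.22) and MFA2 (2.59) kept their call and STE6 (0.53) and BAR1 (0.76) lost it. Phosphate starvation was called lower, at −0.85 over 14 genes (−0.74 by print-tip loess), with 6 that fell and 2 that rose. PHO86 (−1.56 ± 0.40) and VTC4 (−1.55 ± 1.08) fell, as did the phosphatases PHO11 (−2.59 ± 0.10) and PHO8 (−1.87 ± 0.03), where bdf1Δ was not well above background and W303 at least 1.79-fold and 1.30-fold higher. Of these 4, only PHO86 kept its call by print-tip loess (−1.45), which placed VTC4 at −0.96, PHO11 at −0.84 and PHO8 at −0.38. Ribosomal proteins were called lower at −1.03 over 132 genes, where 68 fell and 4 rose, but the median was −0.20 by print-tip loess. RPL20A (−3.30 ± 0.05) and RPL17B (−3.24 ± 0.25) fell, as did RPL3 (−3.30 ± 0.20), where bdf1Δ was not well above background and W303 at least 1.95-fold higher. By print-tip loess RPL20A (−2.51) and RPL17B (−2.62) kept their call and RPL3 (−0.97) lost it.

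The other lists measured in bdf1Δ against W303 were not called. Their medians, with genes that rose and fell, were 0.30 for iron-sulphur and haem enzymes (3 and 2 of 21), 0.09 for sulphate assimilation (0 and 2 of 13), −0.02 for heat shock (7 and 9 of 24) and −0.13 for oxidative stress (4 and 7 of 25). By print-tip loess these medians were 0.06, −0.07, 0.08 and 0.09. The respiratory chain gave −0.48 (6 and 11 of 31), mitochondrial carriers and ribosome −0.19 (1 and 7 of 26), trehalose and glycogen 0.24 (2 and 1 of 14), ribosome biogenesis −0.03 (3 and 7 of 33) and general amino acid control −0.35 (3 and 10 of 30), against 0.03, 0.08, 0.13, 0.04 and −0.08 by print-tip loess. Cell wall and anaerobic genes gave −0.03 (5 and 5 of 17), sterol synthesis −0.61 (3 and 8 of 20), galactose, maltose and hexose transport −0.76 (1 and 4 of 11), selectable markers −0.61 (1 and 1 of 5), chromatin partners 0.23 (1 and 2 of 11) and seripauperins 0.07 (2 and 1 of 9), against 0.18, −0.42, −0.27, −0.37, 0.00 and −0.20 by print-tip loess. The sodium and hyperosmotic lists had print-tip medians of 0.09 and 0.05. Mitochondrially encoded genes, meiosis and mating type alpha had 0, 3 and 1 measured members.

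Of the genes measured in both comparisons, 12 rose and 31 fell in bdf1Δ+HAL2, which limits how many can move opposite to the 662 lower and 537 higher in bdf1Δ. Of the 12, 3 were lower in bdf1Δ, namely FIT2, ARO10 and ENB1, and of the 31, 6 were higher in bdf1Δ. Independent lists would give 2.34 and 4.91 such genes, and the simulation of unchanged strains gave 2.61 and 2.77. The same direction was called for 7 of the genes lower and 2 of the genes higher in bdf1Δ. In bdf1Δhda1Δ, 8 of the 18 genes that rose were lower in bdf1Δ, FIT2, HMX1 and ENB1 among them, and 3 of the 10 that fell were higher, namely FMP16, PHM7 and SSA3, with 522 genes lower and 279 higher in bdf1Δ. Independent lists would give 4.85 and 1.44 and the simulation gave 0.83 and 0.745, while 2 and 3 genes moved in the same direction as in bdf1Δ. For both modified strains the simulated counts run low, since fewer simulated than observed genes passed 2-fold, and cannot weigh the observed ones. By print-tip loess the opposite genes numbered 2 of those lower and 3 of those higher in bdf1Δ for bdf1Δ+HAL2 and 4 and 4 for bdf1Δhda1Δ, and by scale normalization 0 and 1 for each strain. Some other alternatives gave more, and the authors' ratios after centring gave 8 and 16 for bdf1Δ+HAL2. ARO10 (−1.18), FMP16 (1.54), PHM7 (1.02) and SSA3 (1.38) in bdf1Δ against W303 were named after their values were seen. Of these, ARO10 and PHM7 were not well above background in bdf1Δ. For ARO10 W303 was at least 1.15-fold higher, and ARO10 lost its call by print-tip loess (−0.20), as FIT2 (−0.85) and ENB1 (−0.37) did. Correlations of bdf1Δ versus W303 with the other comparisons across genes were r = −0.06 and −0.08, against −0.16 and −0.14 for unchanged strains sharing bdf1Δ. With 1 array of each pair alone the first ran from −0.16 to 0.05 and the second from −0.09 to −0.05.

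By chromosome, genes of VII (0.26) and VIII (0.25) were called higher in bdf1Δ, at 0.10 and 0.07 by print-tip loess. In bdf1Δ+HAL2 genes of chromosome VI were called higher (0.10) and those of XVI lower (−0.03), neither of them by print-tip loess, and in bdf1Δhda1Δ no chromosome was called. By median, the outermost 5 genes of each arm by name were lower in all 3 comparisons with the spot filter used. Their medians were −0.46 over 58 genes in bdf1Δ, −0.29 over 72 in bdf1Δ+HAL2 and −0.44 over 43 in bdf1Δhda1Δ, against −0.29, −0.27 and −0.32 by print-tip loess. In bdf1Δ the median was 0.73 without a filter on dim spots, 0.63 with spots not found by the image software kept, and −0.0416 with both channels above background. Without the YRF1, PAU, COS and ERR families and reading frames without a symbol, a choice made after seeing the data, the medians were −0.43 over 17, −0.15 over 16 and 0.24 over 8 genes. None of these 3 was beyond the outer 2.5% of the random lists on each array.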

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

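All tests in this part were chosen after the result was seen, except the test of a dye bias that recurs between arrays.

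Control probes named Y1 to Y8, whose identity the files do not describe, lay outside the comparisons and still gave ratios past 2-fold the same way on both arrays for 7 of the 8 probes in bdf1Δ+HAL2 and for 3 in bdf1Δhda1Δ. Y5 stood at 4.27 ± 0.08 and 1.80 ± 0.04 in these comparisons, and Y6 at 0.46 ± 0.05 and −2.96 ± 0.05. RGI1 drew attention because both arrays of bdf1Δ+HAL2 placed it below bdf1Δ, at a mean of −1.16, and both arrays of bdf1Δhda1Δ above it, at 1.14. By print-tip loess the value in bdf1Δ+HAL2 was −1.07 and no longer past 2-fold on both arrays. The difference between the strains was not tested.

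The comparison of bdf1Δ with W303 called 1266 genes, far more than the other comparisons. Only 23.4% of these calls, or 296, were also made when each block of the slide was normalized on its own, so position on the slide is a candidate explanation for many of them. The bdf1Δ channel was not well above background in 56.6% of the lower and 6.81% of the higher genes, against 42.2% of all measured genes, but a dim bdf1Δ signal is part of what makes a gene lower, so a weak channel and a difference between the strains cannot be told apart by these shares. A dye bias that recurs between arrays is argued against, since the called genes had a median bias of −0.0659 in the direction of their call on the bdf1Δ+HAL2 pair and −0.01 on the other pair. Across genes that bias correlated with the bdf1Δ versus W303 ratios at Pearson r = −0.29 and −0.05, where a recurring bias would give a positive r. The cause of that relation was not tested. A difference between the strains stays open for the calls made by both methods, and 1 array without exchanged dyes cannot exclude a bias of its own.

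The iron uptake list was higher in both modified strains. The lowest list median among the 4 arrays was 0.76. A list called higher must lie high in both dye orientations, so this is no separate test of dye bias. The normalization or background correction is argued against by the lowest median among those alternatives, 0.77. A low level in the shared bdf1Δ strain would place the list as far below 0 in bdf1Δ against W303. The median there was −0.29 (−0.45 by print-tip loess) for the 12 members measured with bdf1Δhda1Δ, against the 1.45 to be explained, and −0.0476 (−0.37) for the 16 measured with bdf1Δ+HAL2, against 0.81, with SDs of the members of 0.862 and 0.832. As that comparison is 1 unevenly hybridised array, a low bdf1Δ level and a change in the modified strains cannot be told apart.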

How the results depend on the processing

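Of the alternatives in this part, keeping spots not found by the image software, centring the authors' ratios of bdf1Δ versus W303 and leaving out multigene families were chosen after the result was seen.

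No paired analysis was possible because the labels name no cultures shared between strains. Leaving out near-identical gene copies was not run because no sequences are given, and no block of replicates exists to adjust for. BDF1 has no value with both channels above background.

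With both channels above background 101 of 130 named gene values and 56 of 60 list medians could be computed, and INO1, KEX1, PRM1, SHH3 and TIS11 are among the genes without one. Under the alternatives that gave a value, the named genes kept the direction of their ratio for 47 of 47 in bdf1Δ+HAL2, 34 of 34 in bdf1Δhda1Δ and 38 of 49 in bdf1Δ versus W303. A change of direction was counted for called genes only, so named genes without a call always count as kept. The called lists kept their direction for 10 of 10, 11 of 11 and 2 of 3, in the same order. This compares the sign of the list median and not whether the list stayed called. With unmatched random lists, the counts of lists called higher or lower moved by more than 1.5-fold in 2 cases and not in 4. With the list mean in place of the median, they moved in 1 case and not in 5. The 1 list and 7 of the genes that changed direction did so with the authors' ratios. Those are not centred for bdf1Δ versus W303, which lowers the ratios there at large. The cause of the shifts below was not tested.

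Print-tip loess turned SSB1 (0.19), AHP1 (0.0886) and ENA5 (0.15) above 0 in bdf1Δ versus W303, where 219 genes were then higher and 228 lower. BDF1 moved to −1.01. The chromosome ends moved to −0.27 in bdf1Δ+HAL2 and −0.32 in bdf1Δhda1Δ, and 0 chromosomes were called in bdf1Δ+HAL2. Of the genes higher in bdf1Δ, 3 were opposite in bdf1Δ+HAL2, of those lower, 4 were opposite in bdf1Δhda1Δ, and the correlation of bdf1Δ versus W303 with bdf1Δhda1Δ was −0.11.

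The authors' ratios of bdf1Δ versus W303, which are not centred, gave 31 genes higher and 2873 lower. They turned the list of mating type a (−0.58), FRE1 (−0.31), FRE2 (−1.09), BAR1 (−0.75), MFA2 (−1.04), FMP16 (−0.60), PHM7 (−1.48) and SSA3 (−0.97) below 0, and moved BDF1 to −6.37 and the chromosome ends to −2.62. HAL2 moved to 3.47 in bdf1Δ+HAL2, where 0 chromosomes were called, and the ends moved to −0.39 in bdf1Δhda1Δ. Of the genes higher in bdf1Δ, 1 and 0 were opposite in bdf1Δ+HAL2 and bdf1Δhda1Δ, and of those lower 16 and 16. After centring that array, 1048 genes were higher and 1137 lower, BDF1 stood at −4.01 and the ends at −0.26. The list of mating type a and the genes turned below 0 kept their direction after centring, and of the named genes only VTC4 turned, to 0.60. Opposite genes then numbered 16 and 5 of those higher in bdf1Δ, and 8 of those lower in bdf1Δ were opposite in bdf1Δ+HAL2.

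Scale normalization between arrays left 2 genes higher and 28 lower in bdf1Δ versus W303, with BDF1 at −0.27 and the chromosome ends at −0.15. It gave 32 genes higher in bdf1Δ+HAL2, with HAL2 at 4.33 and the ends at −0.35, and 45 higher and 36 lower in bdf1Δhda1Δ, with the ends at −0.66. Opposite genes numbered 1 and 0 in bdf1Δ+HAL2 and 1 and 0 in bdf1Δhda1Δ, for those higher and lower in bdf1Δ.

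Without a filter on dim spots, 1564 genes were higher in bdf1Δ versus W303, 6 chromosomes were called and the ends turned to 0.73. Genes past 2-fold in opposite directions numbered 3 in bdf1Δ+HAL2 and 259 in bdf1Δhda1Δ. With the filter, mostly the finding of spots by the image software limited the genes measured to 4266 and 2074 of 6388 in these comparisons. The ends moved to −0.27 and −0.38 in these comparisons, 0 chromosomes were called in bdf1Δ+HAL2, and 18 and 5 genes higher in bdf1Δ were opposite. Correlations moved to −0.22 between bdf1Δ and bdf1Δhda1Δ and 0.23 between the modified strains. Keeping spots the image software had not found gave 1247 genes higher in bdf1Δ, 5 chromosomes called and the ends turned to 0.63. In bdf1Δhda1Δ 7 genes were then opposite between arrays and the ends stood at −0.32, in bdf1Δ+HAL2 0 chromosomes were called, 18 and 5 genes higher in bdf1Δ were opposite, and the correlations were −0.11 and 0.20. With both channels above background, 280 genes were lower in bdf1Δ with the ends at −0.0416, 0 chromosomes were called there and in bdf1Δ+HAL2, and 1 and 3 genes lower in bdf1Δ were opposite.

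Without background subtraction, 1 chromosome was called in bdf1Δ+HAL2, the ends moved to −0.38 in bdf1Δhda1Δ, and 1 and 5 genes lower in bdf1Δ were opposite. Normexp with offset 0 gave 1 chromosome in bdf1Δ+HAL2, ends at −0.46 in bdf1Δhda1Δ, BDF1 at −1.12, and 6 genes lower in bdf1Δ opposite in bdf1Δ+HAL2. Plain subtraction gave 1 chromosome each in bdf1Δ versus W303 and bdf1Δhda1Δ, ends at −0.48 in the latter, BDF1 at −1.27, and 6 genes lower in bdf1Δ opposite in bdf1Δ+HAL2. Median centring gave 0 chromosomes in bdf1Δ+HAL2, HAL2 at 3.54, BDF1 at −1.16, ends at −0.43 in bdf1Δhda1Δ, and correlations of −0.0335 between bdf1Δ and bdf1Δhda1Δ and 0.32 between the modified strains. Leaving out saturated spots gave 1 chromosome in bdf1Δ+HAL2. The median of repeat spots gave 1 chromosome in bdf1Δ and 1 in bdf1Δ+HAL2, with ends at −0.44 in bdf1Δhda1Δ.

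At 1.5-fold, 1010 genes were higher and 1063 lower in bdf1Δ versus W303, 96 and 161 in bdf1Δ+HAL2, and 59 and 48 in bdf1Δhda1Δ. Opposite genes then numbered 44 and 36 in bdf1Δ+HAL2 and 16 and 21 in bdf1Δhda1Δ, for those higher and lower in bdf1Δ. At 3-fold the counts were 185 and 347, 4 and 6, and 6 and 4, with 0 opposite genes in every case. On the mean of the pair, 30 genes were higher in bdf1Δ+HAL2.

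With 1 array of each pair alone, 35 to 36 genes were higher and 60 to 70 lower in bdf1Δ+HAL2, 0 to 1 chromosomes were called, and the ends ran from −0.33 to −0.23, and from −0.42 to −0.39 in bdf1Δhda1Δ. Opposite genes numbered 7 to 10 of those higher and 6 to 7 of those lower in bdf1Δ for bdf1Δ+HAL2, and 3 to 7 of those higher for bdf1Δhda1Δ. The correlation of the modified strains was 0.25 to 0.27. Without multigene families and unnamed reading frames, the ends moved to −0.15 in bdf1Δ+HAL2 and turned to 0.24 in bdf1Δhda1Δ.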

Other observations

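The test of the genes of phospholipid synthesis in this part was chosen before its result was seen, and the tests on KEX1 after.

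The array carried 144 repeat spots of SSA4, an inducible Hsp70 gene, among its control spots. They gave −0.93 ± 0.12 and −0.74 ± 0.16 (SD of spots) on the arrays of bdf1Δhda1Δ against bdf1Δ, neither of them past 2-fold, while SSA3 of the same family fell (−1.49). In bdf1Δ+HAL2 the SSA4 spots lay at −0.08 and −0.04. The 144 spots of ACT1, the actin gene, lay at 0.28 and 0.27 in bdf1Δ+HAL2 and at −0.01 and −0.13 in bdf1Δhda1Δ. Against W303 the ACT1 spots of bdf1Δ averaged −2.08 with an SD of 1.46, and −1.06 with an SD of 1.07 after print-tip loess, so repeat spots of one gene disagreed widely on that slide.

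INO1 rose in bdf1Δ+HAL2, and other genes of phospholipid synthesis may have moved with it. A list of 16 such genes without INO1, written after INO1 had been seen, had 15 measured members with a median of 0.60. Of these, 14 were above 0 and 0 were called. The median exceeded 100% of the matched random lists on both arrays, the result the hypothesis required. ITR1, the inositol transporter, was the highest of them at 1.05. No technical explanation was tested for this pattern.

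KEX1 had the lowest mean ratio in bdf1Δ+HAL2, where that strain exceeded background in 3 of 3 spots on array 1 and in 0 on array 2, so the size of the fall is uncertain. The ratio was −3.87 with both channels above background on array 1 and −3.43, with net intensities of 166 and 3624, in the other orientation. The call itself required a fall past 2-fold in both orientations, so this is no separate test of a dye or spot artefact. Loss of a larger region is argued against by the nearest measured genes by position in the R64 gene table, CHC1 and ARO8, whose lowest ratio was −0.10. A level raised in bdf1Δ would place KEX1 as far above 0 against W303, where it stood at 0.643 (0.149 by print-tip loess), but on 1 array and with bdf1Δ above background in 1 of 3 spots. In bdf1Δhda1Δ against bdf1Δ it stood at −0.12 and 0.32, which a level raised by the shared deletion would give as well, so this and a change in bdf1Δ+HAL2 cannot be told apart.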
